A study of Mus musculus with 5 samples.

How the data were processed

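Reduced representation bisulfite libraries of 5 mouse tissues were used, 1 of muscle as control and 4 of teratomas, which the labels name by culture condition as P5_2iL, P5_2iL_F, P5_a2iL_1 and P5_LCDM_1. The last 2 are written here as P5_a2iL and P5_LCDM. The deposited files give, for each CpG cytosine, its methylation level in percent, with the 2 strands of a CpG on separate lines and no read count. Per the submitters' processing notes, Trim Galore 0.6.4 and Bismark were used and the genome build was mm10. The version of Bismark, the coverage minimum and the settings of the methylation calls are not given in the sources used here. Per the labels, DNA was prepared with a DNeasy kit, libraries were amplified by PCR and size-selected on a gel, and sequencing used the Illumina Genome Analyzer. Reads from the same original molecule cannot be recognised in these files.

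The depth of each library is known only as the number of cytosines listed, from 4017125 in muscle to 5323090 in P5_2iL_F. The coverage behind a single percent is unknown, so no confidence interval was computed and no coverage minimum was set. The planned Fisher tests on methylated and unmethylated reads, and the planned intervals of shares, need such counts and were replaced by the size rule alone. This rule asks for a difference of mean level of 25 percentage points or more over cytosines measured in both libraries, with 3 or more of them in the window. Each cytosine had equal weight. It is not a test, and its calls describe pairs of libraries.

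The precision was estimated from the strands, an addition made after the data were seen. A pair of neighbouring listed positions with no further neighbour was taken as the 2 strands of a CpG, which assumes that the files count starts from 0. This could not be checked against a genome. Over 1 kb tiles with 3 or more such pairs measured in both libraries, the share of tiles 25 points apart was computed between opposite strands of the 2 libraries and between the strands within each library. The per cytosine spread was the root mean square of the strand difference divided by the square root of 2. Strands of 1 library share the animal, the DNA and the library preparation, so this background leaves out biological spread and the spread between library preparations.

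Mean levels were taken over 3079380 autosomal cytosines listed in all 5 libraries. CpG density was the number of listed cytosines within 100 bp. Gene positions came from a RefSeq gene table of GRCm38.p6, the same build as mm10, with 21887 protein coding genes. The table used here gives the start and end of each gene and no strand, so the planned promoter windows were replaced. For each gene the end with more listed cytosines was used, from 1000 bp outside to 500 bp inside the gene, and the start was taken where both had as many (3471 genes). Such a window can lie at the 3' end of a gene. Windows of neighbouring genes can overlap.

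Comparisons were each teratoma against muscle (4), the other teratomas against P5_2iL (3), and the 3 remaining pairs. Fixed 1 kb tiles, single cytosines, gene ends, 22 imprinted germline windows, 4 Hox clusters and the protocadherin cluster were compared. There were 13 gene lists, on pluripotency, germline genes kept off by methylation, skeletal muscle, neural genes, endoderm and epithelium, mesenchyme and cartilage, blood and immune genes, endothelium, trophoblast, imprinted genes, tumour suppressors, Polycomb-regulated developmental genes and the DNA methylation machinery. The median difference of each list was placed among 10000 random lists of the same size drawn from gene ends in the same of 20 bins of mean level. The percentile describes these libraries and is not a p-value. The groups, windows, lists, thresholds and a set of other settings were fixed before the data were examined.

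Named genes were chosen by a rule of the same date. It takes the 10 called gene ends with the largest difference in each direction per comparison among those with 5 or more cytosines in all 5 libraries, 5 tiles in each direction, all windows of the fixed regions, and the called members of each list, at most the 4 with the largest difference. Of the named tiles only 1 is described, and some gene ends that the rule selects are not reported here. A further 5 lists of blood lineages (pan-leukocyte, T cell, B cell, myeloid, and erythroid and megakaryocyte) were written after results had been seen, and the values of 13 of their genes were known by then.

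Computation used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. The tile and window code was tested on simulated data for chromosome 1 with 10 reads per cytosine and 200 changed tiles in each of the 4 comparisons with muscle. Of tiles shifted by 50 points it recovered 97.5% (P5_2iL_F and P5_LCDM) to 99% (P5_a2iL), and of those shifted by 30 points 66% (P5_2iL_F) to 74.5% (P5_LCDM). It called 0.195% (P5_2iL) to 0.390% (P5_LCDM) of unchanged tiles. Real read depths are unknown, so these rates need not hold for the files. The strands within a library differed past the size threshold in 3.34% (P5_2iL) to 10.1% (muscle) of tiles compared with another library. A strand holds only part of the cytosines of a tile, so these shares are not rates of false calls. They and the 4.49% of tiles called for P5_2iL_F against P5_2iL lay far above the simulated share. The simulated share is thus not a false-call rate for the files. Alternatives changed the size threshold, the number of cytosines, the tile and window bounds, the set of cytosines and the random lists. Unplaced contigs were left out, and the mitochondrial genome was used only in a check of bisulfite conversion.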

Results

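DNA methylation was measured by reduced representation bisulfite sequencing, which reads methylation at CpG cytosines in the CpG-rich part of the genome, in mice of the C57BL/6x129S6 background. A teratoma is a tumour that holds differentiated tissues and arises from pluripotent cells. Here 4 teratomas that arose after embryonic stem cells had been placed into tetraploid embryos were compared with muscle as the control tissue. The stem cells came from culture conditions labelled P5_2iL, P5_2iL_F, P5_a2iL_1 and P5_LCDM_1, which the labels do not spell out, and the last 2 are written here as P5_a2iL and P5_LCDM. Each of the 5 groups holds 1 library, so every difference compares libraries, not conditions, and has no replicate check.

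The muscle file listed 4017125 cytosines, and the P5_2iL, P5_2iL_F, P5_a2iL and P5_LCDM files listed 4892985, 5323090, 4446459 and 4601508. All 5 libraries shared 3079380 autosomal cytosines. The files hold a percent per cytosine and no read count, so the depth behind each value is unknown and no interval is given. The only error measure is the difference between the 2 strands of the same CpG within a library. It covers sampling and technical spread within that library, and not the spread between library preparations or between animals. Per cytosine this spread was 18.3 percentage points in muscle, 14.5 in P5_2iL, 15.4 in P5_2iL_F, 17.6 in P5_a2iL and 17.2 in P5_LCDM.

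Mean methylation over the shared autosomal cytosines was higher in each teratoma library than in muscle, where it was 42.7%. It was 49.5% in P5_2iL, 48.9% in P5_2iL_F, 46.5% in P5_a2iL and 44.4% in P5_LCDM. Cytosines above 80% made up 43.1% of the shared set in P5_2iL and 41.4% in P5_2iL_F, against 31.4% in muscle. In P5_LCDM that share was 30.7%, and 26.8% of its cytosines lay from 20 to 80%, against 21.7% in muscle and 13.4% in P5_2iL. These are descriptions of 5 libraries with no test between conditions.

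The libraries differed most in CpG-poor DNA. Where fewer than 5 cytosines were listed within 100 bp, the mean level was 69.5% in muscle, 81.1% in P5_2iL, 80.1% in P5_2iL_F, 75.1% in P5_a2iL and 69.3% in P5_LCDM. Where 30 or more were listed, the order was different, with 3.09% in muscle, 4.05% in P5_2iL, 4.03% in P5_2iL_F, 4.31% in P5_a2iL and 5.01% in P5_LCDM. Outside protein coding genes the level was 64.0% in muscle, 73.6% in P5_2iL and 63.4% in P5_LCDM. At the CpG-richer ends of genes it ranged from 5.16% in muscle to 6.67% in P5_LCDM.

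**Figure D1:**
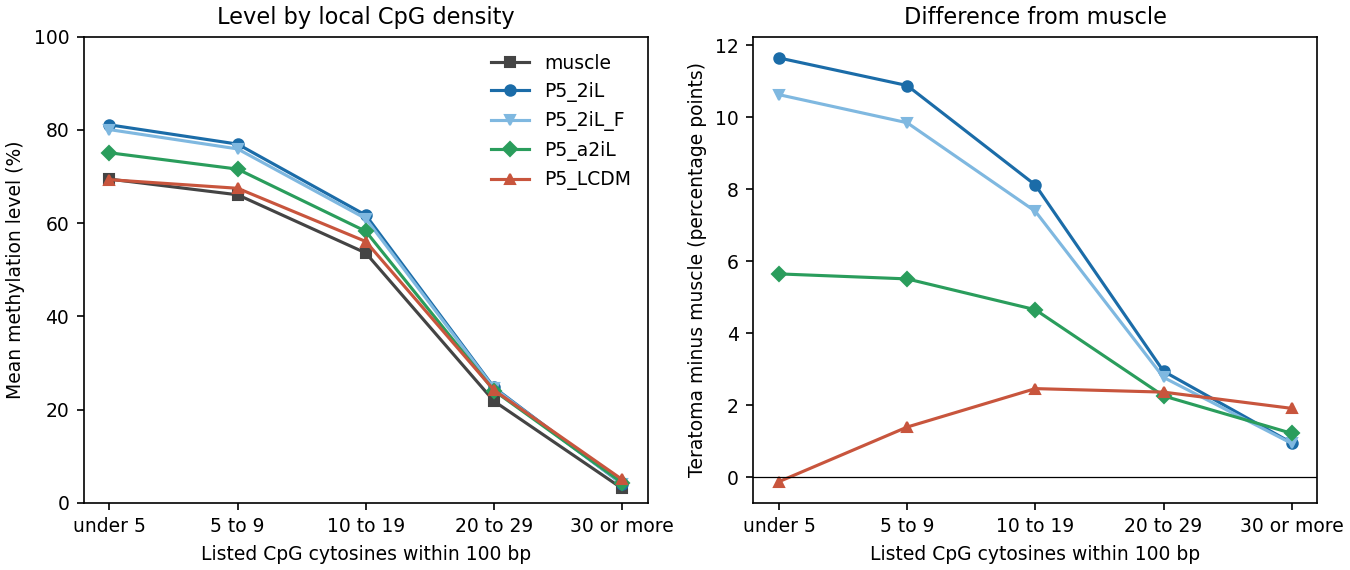
Mean methylation level in percent of each library (left) and its difference from muscle in percentage points (right) against the number of listed CpG cytosines within 100 bp, over autosomal cytosines shared by the 5 libraries, 1 library per group. In the CpG-poorest class P5_2iL lay at 81.1% and P5_LCDM at 69.3%, and in the CpG-densest class P5_LCDM was the highest at 5.01%.

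Windows were compared by a size rule, a difference of 25 percentage points or more over cytosines measured in both libraries, with 3 or more of them per window. The strands of 1 library gave a background for this rule over 1 kb tiles. Opposite strands of P5_2iL and muscle differed by 25 points or more in 20.4% of tiles, while the strands within these libraries did so in 6.39% on average. For P5_2iL_F, P5_a2iL and P5_LCDM against muscle the shares were 19.5%, 15.7% and 18.1%, with within-library means of 6.92%, 8.83% and 8.78%. Against P5_2iL the share was 18.6% for P5_LCDM and 11.5% for P5_a2iL, over backgrounds of 5.50% and 5.83%. For P5_2iL_F against P5_2iL it was 4.06%, within 0.119 percentage points of the background of 3.94%. Across shared cytosines, which are not replicates, the Pearson correlation of P5_2iL_F with P5_2iL was 0.948, and the other pairs ranged from 0.823 to 0.905.

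**Figure D2:**
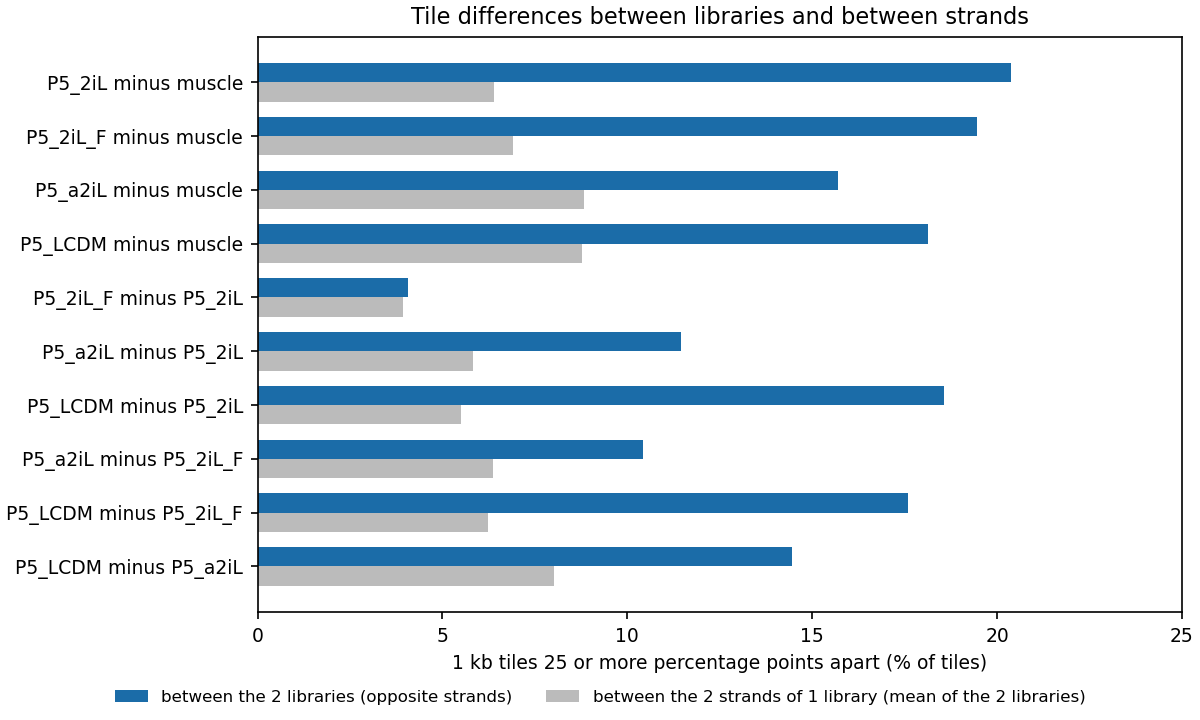
Share of 1 kb tiles in percent that differed by 25 or more percentage points between opposite strands of 2 libraries (blue) and between the strands of a library, averaged over the 2 libraries (grey), for the 10 comparisons. The bars of P5_2iL_F minus P5_2iL end at 4.06% and 3.94%, while P5_2iL minus muscle ends at 20.4% and 6.39%.

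The first question was how the P5_2iL teratoma differed from muscle. Of 32 measured skeletal muscle genes 10 were higher in the teratoma and 0 lower, while the median difference of the list stood at percentile 93.4, inside the central 95% of random lists. Ldb3, which encodes a Z-disc protein, lay at 79.4% against 14.8% at its CpG-richer end, and the calcium store gene Casq1 at 96.3% against 14.3% over only 3 cytosines. The troponin I genes Tnni1 and Tnni2 lay at 88.6% against 39.6% and at 84.3% against 35.8%. Past the rule, blood and immune genes mostly went the other way, with 5 of 13 measured genes lower and 1 higher. The median difference over this list was only -1.27 points.

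Rac2, a small GTPase gene of blood cells on chromosome 15 (mm10, 78572283 to 78573783), was at 0% in P5_2iL against 94.4% in muscle over 8 cytosines. The leukocyte integrin gene Itgb2 was at 0.617% against 70.5%, and Vav1, a guanine nucleotide exchange factor of blood cells, at 0.582% against 38.9%. Spi1, which encodes a transcription factor of myeloid and B cells, was higher, at 95.6% against 40.2%. The median difference of this list stood at percentile 0.18 of 10000 random lists matched on level. Of 35 germline genes 5 were higher and 1 lower, and the list stood at percentile 45.5, with Tdrd6 at 88.7% against 31.6%, Stk31 at 100% against 56.5%, Hormad2 at 78.9% against 51.6% and Dmrtb1 at 33.8% against 73.9%. Lefty1 was higher and Gdf3 lower among 23 pluripotency genes. Cldn4 and Cdx1 were higher among 25 genes of endoderm and epithelium, the latter at 64.3% against 12.9% over 115 cytosines. Among 12 endothelial genes Tie1 was higher, at 95.6% against 22.9%, and Eng lower, at 4.26% against 33.7%.

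Among gene ends with 5 or more cytosines in all 5 libraries, the 10 largest rises included Tmem88b at 90.5% against 1.43%, the hormone gene Insl3 at 88.1% against 0% and the homeobox gene Hoxa3 at 98.7% against 12.1%. Lmod3, which encodes a leiomodin of muscle thin filaments, was at 85.1% against 4.64%, and Alox5ap, needed for leukotriene synthesis, at 95.7% against 15.0%. Clec3b lay at 94.8% against 14.8%, and Vill, S100a16, Magix and Gltpd2 completed this group, with rises of 80.4 to 82.1 points. Beside Rac2, the largest declines were at Gm44180 with 5.80% against 98.7%, Arhgap30 with 0.513% against 89.7% and Tifab with 1.36% against 89.4%. Slc12a3, N4bp2l1, Ripor2, Havcr2, Tspoap1 and Tnfsf14 were lower by differences from -79.5 to -71.5 points. Here and in the comparisons below, lists given without a percentile lay within the central 95% of random lists. In all, 706 gene ends were higher and 177 lower of 14854 measured, and 40248 tiles were higher and 7894 lower of 230684. The gene table gave no strand, so a gene end can be either end of the gene. Of 112817 tiles with 3 or more strand pairs in both libraries, 11392 were higher and 2215 lower at 25 points on each strand alone. In 243 others the strands passed in opposite directions.

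Other lists had few members past the rule in P5_2iL. Neural genes had 1 of 32 higher (Gfap), with the list at percentile 97.65, genes of mesenchyme and cartilage 2 of 27 (Col3a1 and Thy1), and trophoblast genes 1 of 12 (Elf5). Tumour suppressor genes had 2 of 32 higher (Gstp2 and Dkk3) and 1 lower (Runx3). Imprinted genes had 3 of 25 higher, Mcts2, Peg10 and Sgce, of which the last 2 share their window. Of 56 Polycomb-regulated developmental genes 0 passed the rule, with a median difference of 2.32 points at percentile 99.2, and 0 of 15 genes of the DNA methylation machinery passed. A tile within Hspb6, a small heat shock protein gene of muscle, on chromosome 7 (30554001 to 30555000) was at 100% in P5_2iL and 0% in muscle over 10 cytosines.

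**Figure D3:**
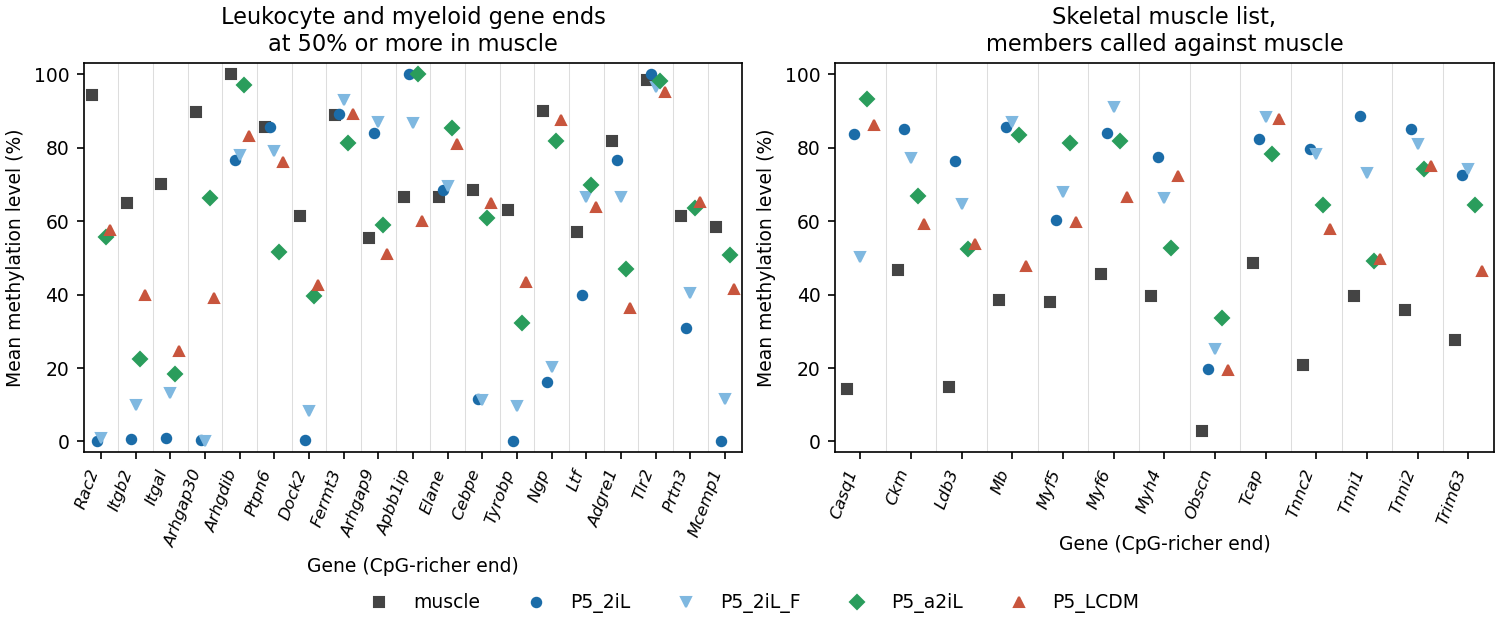
Mean methylation level in percent of each library at the CpG-richer end of leukocyte and myeloid genes that were at 50% or more in muscle (left) and of skeletal muscle genes that passed the size rule against muscle in at least 1 teratoma (right), 1 point per library. Rac2 lay at 94.4% in muscle and at 0% in P5_2iL, whereas Tlr2, chosen after its values were seen, lay at 95.1% or more in all 5 libraries. The left panel was picked on the muscle level and the right panel on the difference, so neither shows a typical gene.

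The P5_2iL_F teratoma was compared with muscle in the same way. Of 31 measured skeletal muscle genes 12 were higher and 0 lower, and the list stood at percentile 99.1. The myoglobin gene Mb lay at 86.1% against 41.5%, Tnnc2, which encodes fast troponin C, at 74.5% against 20.8% and Ldb3 at 62.4% against 14.8%, and Casq1 was also higher over 3 cytosines. Of 13 blood and immune genes 4 were lower and 1 higher, at percentile 0.2. Rac2 was at 1.14% against 94.4%, Itgb2 at 9.83% against 70.5% and Csf1r, a macrophage growth factor receptor gene, at 25% against 66.7% over 4 cytosines, while Spi1 was at 69.8% against 33.3%.

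Of 35 germline genes 6 were higher, among them Stk31 at 100% against 56.5%, Mov10l1 at 97.8% against 62.5% and Tdrd6 at 80.9% against 31.6%. Dmrtb1 was lower, at 25.7% against 73.9%, and the list stood at percentile 66.3. Of 25 imprinted genes 5 were higher, with Mcts2 at 89.6% against 30.6%, Nap1l5 at 70.6% against 41.9% and Dlk1 and Sgce as further members. Dkk3, Gstp2 and Trp53 were higher among 33 tumour suppressor genes, the last over only 4 cytosines. Lefty1 was higher among 23 pluripotency genes, Cldn4 and Cdx1 among 25 of endoderm and epithelium, Col3a1 among 27 of mesenchyme and cartilage, and Lhx3 among 56 Polycomb-regulated genes, a list with a median difference of 2.86 points at percentile 99.8. Tie1 was higher and Eng lower among 12 endothelial genes, and 0 neural, trophoblast and methylation machinery genes passed.

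Insl3 had the largest rise, at 94.4% against 0%, followed by Vill, Ccdc170, Cbfa2t3, Hoxa3 and Tmem88b. Mamstr, a transcriptional coactivator gene of muscle, lay at 94.4% against 10.9%, and Musk, the receptor kinase gene of the neuromuscular junction, at 94.8% against 16.4%. Lmod3 and Gm7030 were higher by 82.3 and 80.6 points. After Rac2 the largest declines were at N4bp2l1 with 0% against 89.5%, Gm44180 with 11.2% against 98.7% and Arhgap30 with 0% against 81.0%. Tifab, Tspoap1, Gm42166, Slc12a3, Arhgef18 and Havcr2 followed. In all, 673 gene ends were higher and 164 lower of 14924, and 39100 tiles were higher and 8156 lower of 238460. Of 117772 tiles with strand pairs, 10605 were higher and 2004 lower on each strand alone.

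The P5_a2iL teratoma differed from muscle at fewer windows. Of 32 skeletal muscle genes 8 were higher and 0 lower, at percentile 99.5, with Mb at 82.7% against 38.6%, Myf5, a myogenic regulator, at 81.2% against 37.5%, Ldb3 at 46.7% against 4.69% and Casq1 over 3 cytosines. Of 11 blood and immune genes 3 were lower, Itgb2 at 22.5% against 70.5%, Rac2 at 55.6% against 94.4% and Runx3 at 35.7% against 73.0%. The median of that list stood at percentile 6.98, inside the central 95% of random lists. The imprinted gene Peg10, which shares its window with Sgce, lay at 85.7% against 13.1% over 49 cytosines.

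Of 35 germline genes 3 were higher (Tdrd6, Stk31 and Hormad2) and 0 lower, and the list stood at percentile 98.96. Of 25 imprinted genes 4 were higher, including Mcts2 at 82.4% against 30.6% and Ndn at 47.1% against 10.5%. Pecam1, an adhesion molecule gene of endothelium, was at 76.0% against 29.6%, and Tie1 was the other higher member of 12. Dkk3, Dapk1 and Gstp2 were higher among 32 tumour suppressor genes, with Dapk1 at 31.6% against 0.251%, and Runx3 was lower. Lefty1, Gfap, Cldn6, Col3a1 and Tfap2c were each the only higher member of their lists (pluripotency, neural, endoderm and epithelium, mesenchyme and cartilage, and trophoblast). Of 56 Polycomb-regulated genes and 15 genes of the methylation machinery 0 passed.

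Eif2s3y, a translation initiation factor gene on the Y chromosome (1009562 to 1011062), lay at 75.8% in P5_a2iL and 0% in muscle over 16 cytosines. In the other teratomas it lay at 12.5% (P5_LCDM) to 21.4% (P5_2iL_F). Tmem88b, Cldn34c1, Magix, Hoxa3, Angpt2 and Musk were higher by 68.8 to 81.1 points, as was the protamine gene Prm1 at 78.8% against 7.50%. The lower gene ends were led by N4bp2l1 at 4% against 89.5%, Zar1l at 23.3% against 100%, Vpreb3 at 40% against 100% and the retinoic acid receptor gene Rara at 0% against 58.3%. Itgb2, Eef1akmt2, Itgal and Psg28 were also lower, with the integrin gene Itgal at 21.1% against 67.4%. In all, 465 gene ends were higher and 126 lower of 14796, and 25627 tiles were higher and 7740 lower of 227898. Of 111386 tiles with strand pairs, 5553 were higher and 916 lower on each strand alone.

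The P5_LCDM teratoma had nearly as many lower as higher tiles against muscle, 18544 and 22181 of 234995. Of 32 skeletal muscle genes 5 were higher and 0 lower, at percentile 98.2, with Casq1 over 3 cytosines, Tcap at 87.9% against 48.5%, Tnni2 at 73.6% against 35.8% and Tnnc2 at 62.5% against 20.8%. Of 56 Polycomb-regulated developmental genes 2 were higher, the kidney and thyroid regulator Pax8 at 88.8% against 28.6% and Pax2 at 29.1% against 1.48%. The median difference of that list was 6.01 points, the highest percentile of all at 100. Endothelial genes had a median difference of -2.97 points at percentile 0.06, with Eng, a TGF-beta co-receptor gene, at 4.63% against 33.7% and Tie1 at 60.4% against 22.9%.

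Of 14 blood and immune genes 4 were lower, Rac2 at 57.6% against 94.4%, Itgb2 at 38.3% against 70.5% and Runx3 at 54.3% against 85.7% among them. Hba-a1 was higher over only 4 cytosines, and the list stood at percentile 40.8. Lefty1 and Nodal, both of the Nodal signalling pathway, were higher among 23 pluripotency genes, Nodal at 33.7% against 0%, and Gdf3 was lower. The keratin gene Krt8 was lower, at 38.8% against 72.3%, and Cldn4 and Cldn6 were higher among 25 genes of endoderm and epithelium. Col3a1 and Col1a1 were higher among 27 genes of mesenchyme and cartilage, Dlx1 among 32 neural genes and Nnat among 25 imprinted genes. Of 35 germline genes Hormad2 was higher and Dmrtb1 lower, and of 33 tumour suppressor genes Dkk3 was higher and Runx3 lower. Trophoblast genes and genes of the methylation machinery had 0 members past the rule.

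Hoxa3 had the largest rise, at 94.2% against 12.1%, and Hoxb6 lay at 77.4% against 8.53%. Ltbp3, Cldn34c1, Mamstr, Map3k7cl, Prss57, Fgd1, Insl3 and Clec3b were higher by 63.3 to 78.5 points. Plvap, an endothelial gene of fenestral diaphragms, had the largest decline, at 9.57% against 73.7%. Fxyd7, Enthd1, Slc29a2, Vpreb3, Tcl1b1, Ssxb8, Cep70 and Havcr2 were lower, with differences from -53.4 to -45.3 points. In all, 490 gene ends were higher and 197 lower of 14909. Of 119208 tiles with strand pairs, 5360 were higher and 3027 lower on each strand alone.

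The next question was how the teratomas from other culture labels differed from P5_2iL. P5_2iL_F differed from P5_2iL at 56 higher and 67 lower gene ends of 15262, and at 5656 higher and 6427 lower tiles of 269357. On each strand alone, 89 tiles were higher and 115 lower, while in 205 others the strands passed in opposite directions. Among gene ends with 5 or more cytosines in all 5 libraries the largest rise was at Ltf, the lactoferrin gene, with 93.3% against 40% over 5 cytosines, and the largest decline at Klra3, with 36% against 90% over 10. Rises of 27.9 to 38.9 points were at Drp2, Abca14, Zfp970, Mef2b, Nrbp1, AI467606, Tmem79, Olfr290 and Hesx1. Tie1, Gm40011, Lpar1, Col5a2, Cnmd, Hcar1, Krtap3-3 and Tubb4a were lower. With tile calls of this pair near the strand background, these gene ends were not separated from sampling spread. The strands agreed at some of them and not at others, with 39.3 and 21.5 points at Nrbp1 and -1.67 and 50 at Hesx1. Among the fixed lists only Tnnt3 was higher, at 100% against 16.7% over 6 cytosines, and Tie1 and Nnat were lower. The Polycomb-regulated list had a median difference of 0.675 points at percentile 99.87, with 0 of 56 members past the rule.

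P5_a2iL was mostly less methylated than P5_2iL, with 7540 tiles higher and 18968 lower of 251201. The largest rises included Arhgap30 at 66.3% against 0.513%, Rac2 at 55.6% against 0% and Ngp, a neutrophil granule protein gene, at 81.8% against 17.3%. Mcemp1 lay at 59.5% against 0%, the immune checkpoint gene Havcr2 at 56.2% against 0% and the chemokine gene Ccl4 at 60.5% against 6.34%. Gm44180, AI467606, Eif2s3y and Scarf1 completed the 10 largest rises. Only Rac2 and Spi1 of 12 measured members of the fixed blood and immune list passed the rule, Spi1 being lower at 54.8% against 95.9%, and the list stood at percentile 92.7, inside the central 95% of random lists.

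Peg10 and Sgce were the higher members of 25 imprinted genes, at 85.7% against 43.1%, and that list stood at percentile 99.8. Eng and Pecam1 were higher and Tie1 and Vwf lower among 13 endothelial genes, a list at percentile 98.1. Cldn4, Cdx1, Col3a1 and Tnni1 were lower, and Cldn6 and Dapk1 higher, in their lists. The pluripotency, germline, neural, trophoblast, Polycomb-regulated and methylation machinery lists had 0 members past the rule. The largest declines were at Gm7030 with 8.33% against 95%, Vill with 6.25% against 82.1% and Zar1l with 23.3% against 97.1%. Nxnl1, C77080, Krt80, Myo1c, Vpreb3 and S100a6 were also lower, with differences from -64.6 to -50.5 points. In all, 168 gene ends were higher and 311 lower of 15105. Of 122953 tiles with strand pairs, 1418 were higher and 2828 lower on each strand alone.

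P5_LCDM was mostly less methylated than P5_2iL, with 7442 tiles higher and 41968 lower of 253836. The lower members of the fixed lists included Mb at 47.8% against 85.7%, Tnni1, Ckm and Myh7 of 32 skeletal muscle genes, and Tdrd6, Stk31 and Sycp3 of 35 germline genes. Of 25 genes of endoderm and epithelium 4 were lower, including Krt8, Epcam and Cdx1, and Cldn6 was higher, with the adhesion molecule gene Epcam at 60.4% against 90.9%. Nodal and Tdgf1, its co-receptor gene, were higher, at 35.3% against 7.28% and 56.4% against 29.3%. Rac2 and Itgb2 were higher, at 57.6% against 0% and 38.3% against 0.617%, among 14 blood and immune genes, and 3 were lower, including Runx3 and Cd3e.

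Of 56 Polycomb-regulated genes Pax8 was higher, at 88.8% against 50%, and the list stood at percentile 99.6. Stmn2 and Dlx1 were higher among 33 neural genes, Sp7 was higher and Col3a1 and Meox1 lower among 28 of mesenchyme and cartilage, and Tie1 and Mcts2 were lower in theirs. Trophoblast and methylation machinery genes had 0 members past the rule. Dgki lay at 87.7% against 12.4%, Gtsf1l at 77.2% against 7.73%, Sh2b2 at 70.2% against 1.25% and Rara at 68.2% against 0%. Gm42166, Ngp, Prss57, Eid3, Gm44180 and Tmem79 were higher by 58.0 to 66.7 points. Magix lay at 16.7% against 96.3%, Cldn15 at 27.1% against 99.2%, Vill at 12.5% against 82.1% and Btnl9 at 29.1% against 96.0%. Hcar1, Sh3d21, Mcts2, Pfn1, Vmo1 and Eva1b followed, and the windows of Sh3d21 and Eva1b overlap. In all, 196 gene ends were higher and 489 lower of 15144. Of 127902 tiles with strand pairs, 2075 were higher and 9449 lower on each strand alone.

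The remaining teratoma pairs were compared by counts. P5_a2iL against P5_2iL_F had 134 gene ends higher and 249 lower, P5_LCDM against P5_2iL_F 183 and 463, and P5_LCDM against P5_a2iL 200 and 269. At single cytosines, 747171 of 3477412 passed the size rule for P5_2iL against muscle and 397414 of 4057686 for P5_2iL_F against P5_2iL. Opposite strands of single CpGs differed by 25 points or more within P5_2iL at 11.3% of pairs and within muscle at 20.2%, so counts of single cytosines hold a large share of sampling spread.

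Imprinted germline regions carry methylation on 1 parental allele, and 22 windows at such regions were fixed as a list. Mcts2, an imprinted retrogene on chromosome 2 (152686855 to 152688934 in muscle), was at 95.1% in P5_2iL against 32.8% in muscle over 82 shared cytosines. It was at 89.6% in P5_2iL_F and 82.4% in P5_a2iL against 30.6% in muscle, whereas P5_LCDM lay at 33.2% against 97.4% in P5_2iL. Peg10 on chromosome 6 (4746914 to 4747491) was at 85.7% in P5_a2iL, 43.1% in P5_2iL and 13.1% in muscle. Impact was higher than in muscle (21.2%) in all 4 teratomas, from 47.8% in P5_2iL to 54.6% in P5_LCDM.

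Cdh15 was higher than the 50.8% of muscle in P5_2iL (85.0%), P5_a2iL (78.4%) and P5_LCDM (87.6%). P5_LCDM was also higher than muscle at Kcnq1ot1 with 65.2% against 31.7% and at Nnat with 73.1% against 36.3%. Snrpn was higher in P5_2iL_F and P5_a2iL, at 53.2% and 58.2% against 26.8%, and Nap1l5 and Peg13 in P5_2iL_F, at 73.1% against 34.9% and 61.2% against 34.6%. Over cytosines of all 5 libraries, the teratomas that did not pass at Cdh15, Snrpn, Nap1l5 and Peg13 also lay above muscle. Snrpn was at 46.5% in P5_2iL and 46.8% in P5_LCDM, and Cdh15 at 72.6% in P5_2iL_F. Which teratomas passed at these windows thus depends on the threshold. Over all measured windows, the mean difference from muscle was positive in every teratoma. It was 11.3 points in P5_2iL, 13.1 in P5_2iL_F, 13.5 in P5_a2iL and 12.7 in P5_LCDM. The standard deviation over windows was 18.3 to 21.3 points. Muscle thus lay below the teratomas on average, and gains near the threshold were not separated from this offset. Peg3 was lower in P5_2iL, at 22.2% against 52.0%. The other teratomas did not pass there but also lay below muscle over cytosines of all 5 libraries. Peg3 was then at 31.1% in P5_2iL_F, 28.0% in P5_a2iL and 46.2% in P5_LCDM, against 49.9% in muscle. Meg3 differed by the rule in P5_2iL_F and P5_LCDM over 12 and 4 cytosines. The number of windows from 25 to 75% was 18 in muscle, 17 in P5_2iL, 18 in P5_2iL_F, 18 in P5_a2iL and 19 in P5_LCDM. Muscle itself was under 25% at 3 windows, Rasgrf1, Peg10 and Impact. P5_2iL_F and P5_2iL differed by the rule at 0 of 22 windows. The strands of a window often differed: at Impact the difference of P5_2iL from muscle was 48.1 points on 1 strand and 5.29 on the other, while at Mcts2 it was 80.1 and 41.8.

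**Figure D4:**
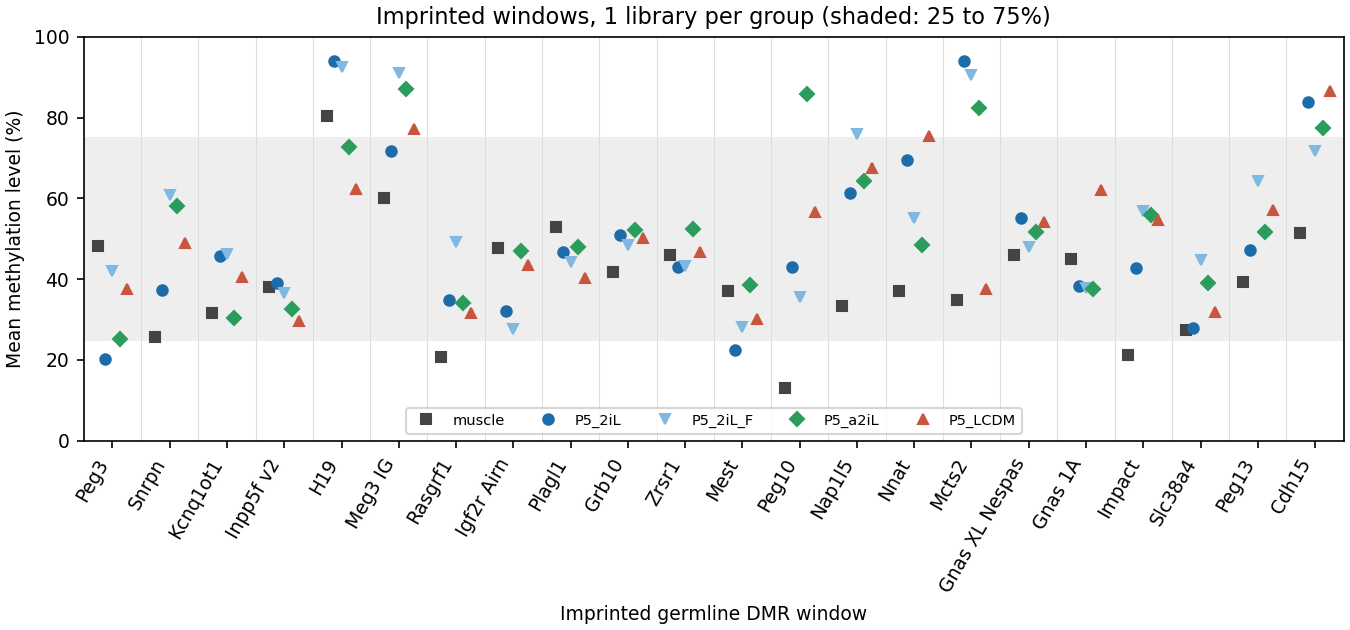
Mean methylation level in percent at 22 imprinted germline windows over all cytosines each library listed in them, 1 point per library, with 25 to 75% shaded. Mcts2 lay at 94.1% in P5_2iL, 90.6% in P5_2iL_F and 82.4% in P5_a2iL, and at 34.7% in muscle and 37.6% in P5_LCDM.

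The Hox clusters hold developmental transcription factor genes, and the protocadherin cluster on chromosome 18 encodes adhesion proteins of neurons. No cluster passed the size rule in any comparison. HoxD (chromosome 2, 74660701 to 74765437) lay at 23.8% in P5_LCDM against 15.7% in muscle, and at 22.8% against 11.2% in P5_2iL, over 2078 and 2384 cytosines. The other teratomas lay below muscle at HoxD, with differences of -3.95, -4.88 and -3.98 points for P5_2iL, P5_2iL_F and P5_a2iL. HoxA lay 8.20 to 9.91 points above muscle in the 4 teratomas and the protocadherin cluster 11.3 to 11.7 points above. HoxB and HoxC lay 2.23 to 10.4 points above.

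Cytosines with 20 or more listed within 100 bp on the X chromosome had a mean level of 16.1% in muscle, 17.6% in P5_2iL, 17.7% in P5_2iL_F, 17.8% in P5_a2iL and 17.7% in P5_LCDM, while on the autosomes they were at 11.7% in P5_2iL and 12.1% in P5_LCDM. Y chromosome cytosines were listed in all 5 libraries, from 13576 in P5_a2iL to 16191 in P5_2iL_F. The mean level of shared Y cytosines was 83.5% in muscle, 88.8% in P5_2iL and 73.7% in P5_LCDM. These values gave no sign of a library from an animal without a Y chromosome.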

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

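The choice of this gene end followed the fixed rule for named genes, while the comparison of directions between teratomas was made after the values were seen. Against muscle, Btnl9 differed by 28.8 points in P5_2iL and by -38.1 points in P5_LCDM, in opposite directions past the size rule. Each value rests on 1 library, the difference between the teratomas was not tested, and no explanation was weighed.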

How the results depend on the processing

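No paired analysis was possible because each group has 1 library, and only the labels P5_a2iL_1 and P5_LCDM_1 carry a number. Of 267 alternative values of reported results 137 stayed the same by the rule for counts or levels and 130 moved. Not run, because the files give no read counts, were coverage minimums of 5 and 20 reads, an upper coverage limit, levels weighted by reads and the Fisher tests. The depth is unknown, which limits single cytosines most. Alternatives on each strand alone and at the other gene end, and the use of cytosines of all 5 libraries for the fixed regions, were chosen after the data were seen. For tiles of 500 bp, autosomes only, gene ends within 500 bp and the CpG-poorer gene end, counts of calls stayed within 1.5 times. For the settings of 10 and 40 points, of 5 cytosines and of each strand alone the counts moved by construction, since fewer or more windows can pass. For the others the cause was not tested.

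Counts follow the order P5_2iL against muscle, P5_2iL_F against muscle, P5_a2iL against muscle, P5_LCDM against muscle, P5_2iL_F against P5_2iL, P5_a2iL against P5_2iL, P5_LCDM against P5_2iL, P5_a2iL against P5_2iL_F, P5_LCDM against P5_2iL_F and P5_LCDM against P5_a2iL. At 10 points the called tiles were 106387, 106914, 91998, 110824, 50405, 89555, 124587, 87234, 125704 and 106043. At 40 points they were 23106, 21604, 12386, 13948, 2648, 7479, 16199, 6700, 15457 and 9203. At 25 points on each strand alone they were 13607, 12609, 6469, 8387, 204, 4246, 11524, 3006, 10254 and 4887. That setting covers only tiles with strand pairs, from 111386 (P5_a2iL against muscle) to 134883 (P5_LCDM against P5_2iL_F). Its counts fall through the smaller set of tiles as well as through the stricter rule. Single cytosines called at 10 points were 1249161, 1296102, 1279393, 1430618, 991683, 1232034, 1430275, 1256281, 1483943 and 1450990. At 40 points they were 462859, 466233, 394640, 461172, 187054, 301412, 432415, 300492, 441495 and 383974. Gene ends called at 10 points were 2139, 2094, 1839, 2126, 729, 1671, 2143, 1498, 2073 and 1816. At 40 points they were 435, 393, 215, 223, 27, 139, 211, 105, 182 and 107. Imprinted windows called at 10 points were 16, 13, 13, 16, 6, 8, 10, 8, 10 and 10.

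With at least 5 cytosines per window the called tiles were 21225 for P5_a2iL minus muscle, 25942 for P5_LCDM minus muscle, 3564 for P5_2iL_F minus P5_2iL, 15468 for P5_a2iL minus P5_2iL, 31434 for P5_LCDM minus P5_2iL, 13333 for P5_a2iL minus P5_2iL_F, 30093 for P5_LCDM minus P5_2iL_F and 19622 for P5_LCDM minus P5_a2iL. Under that setting called gene ends were 56 for P5_2iL_F minus P5_2iL, and called imprinted windows were 1 for P5_LCDM minus P5_2iL and 1 for P5_LCDM minus P5_2iL_F. With cytosines measured in all 5 libraries the called tiles were 3649 for P5_2iL_F minus P5_2iL and 15629 for P5_a2iL minus P5_2iL_F. For P5_2iL_F minus P5_2iL, 1 imprinted window was called with those cytosines, and 1 with 500 bp removed at each end of the window. At 40 points the called imprinted windows were 1 for P5_2iL minus muscle, 1 for P5_2iL_F minus muscle, 2 for P5_a2iL minus muscle, 1 for P5_LCDM minus muscle, 1 for P5_LCDM minus P5_2iL, 1 for P5_LCDM minus P5_2iL_F and 2 for P5_LCDM minus P5_a2iL. At 10 points the called Hox and protocadherin clusters were 1 for P5_2iL minus muscle, 1 for P5_2iL_F minus muscle, 1 for P5_a2iL minus muscle, 2 for P5_LCDM minus muscle, 1 for P5_LCDM minus P5_2iL, 1 for P5_LCDM minus P5_2iL_F and 1 for P5_LCDM minus P5_a2iL. With random lists not matched on level, the lists outside the central 95% were 9 for P5_2iL minus muscle, 7 for P5_2iL_F minus muscle, 10 for P5_a2iL minus muscle, 8 for P5_LCDM minus muscle, 4 for P5_2iL_F minus P5_2iL, 8 for P5_a2iL minus P5_2iL and 8 for P5_LCDM minus P5_2iL. At 10 points, chosen after the data were seen, the excess of tile differences over the strand background, in percentage points, was 18.4 for P5_2iL minus muscle, 15.8 for P5_2iL_F minus muscle, 8.76 for P5_a2iL minus muscle, 13.7 for P5_LCDM minus muscle, 11 for P5_a2iL minus P5_2iL, 20.9 for P5_LCDM minus P5_2iL, 7.91 for P5_a2iL minus P5_2iL_F, 17.9 for P5_LCDM minus P5_2iL_F and 10.6 for P5_LCDM minus P5_a2iL.

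Over every cytosine of each library, the mean level was 45.7% in muscle, 53.7% in P5_2iL, 55.4% in P5_2iL_F, 49.8% in P5_a2iL and 46.8% in P5_LCDM. The cytosines then differ between libraries, and P5_2iL lay below P5_2iL_F, whereas over shared cytosines it lay above.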

Other observations

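All tests of this part, and the 5 lists of blood lineages, were chosen only after the results were seen. Among gene ends at 50% or more in muscle, 5 of 10 pan-leukocyte genes were under 20% in P5_2iL, 5 in P5_2iL_F, 1 in P5_a2iL and 0 in P5_LCDM. Of 9 myeloid genes 4 were under 20% in P5_2iL and 3 in P5_2iL_F. Whatever their muscle level, 6 of 24 pan-leukocyte genes lay 25 points or more below muscle in P5_2iL and 5 above it, including Il16 at 82.5% against 19.7%. Of 18 myeloid genes 5 lay below and 2 above, the latter Cd68 and Spi1. T cell genes (11), B cell genes (6) and genes of erythroid cells and megakaryocytes (4) had 0 members that fell from 50% or more to under 20% in any library, with medians of 90.4%, 93.2% and 53.3% in P5_2iL. By the 25-point rule at any muscle level, 2 of 19 T cell genes lay below muscle in P5_2iL and 3 above. The counts were 0 and 1 of 11 B cell genes, and 1 and 1 of 10 genes of erythroid cells and megakaryocytes. Of all 2012 gene ends at 50% or more in muscle, 69 (3.43%) were under 20% in P5_2iL, and the median of the 1972 gene ends outside these lists was 89.6%. Choosing gene ends by a high muscle level also selects chance high values, which applies to all genes alike.

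The low leukocyte gene ends in P5_2iL and P5_2iL_F were weighed against 2 explanations. Of the 5 low pan-leukocyte genes in P5_2iL, 4 had been seen before the list was written, so their number decides nothing about the share of leukocytes. A P5_2iL library made mainly of leukocytes could not be decided. The median of the pan-leukocyte gene ends was 38.8% with the 4 seen genes and 84.8% over the 6 others. Their levels fell in 2 groups, from 0% (Rac2) to 0.865% (Itgal) and from 76.8% (Arhgdib) to 100% (Apbb1ip), so the median describes neither. The level of these gene ends in leukocytes was not measured, and a window can lie at the 3' end of a gene. Genes picked because they were low may account for part of the pattern, as 7 of the 19 pan-leukocyte and myeloid genes had been seen before, but 3 of the 12 genes not seen before (Dock2, Cebpe and Tyrobp) were also under 20%, while the median of the 12 was 76.7%. The culture condition, the difference the design names, was not tested with 1 library per group.

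At the 25-point rule P5_2iL and P5_2iL_F differed about as often as the strands of 1 library, with an excess of 0.119 percentage points of tiles, and at 10 points the excess was 0.743. This could come from 1 source of DNA behind both libraries. Separate tumours of like composition might also give a low excess, which was not tested. Strand noise too large to show any difference was not the reason, since P5_a2iL against P5_2iL had an excess of 5.62 points by the same measure. The files are not copies of each other, with a correlation of 0.948. Of the 19 pan-leukocyte and myeloid gene ends above, 13 were higher in P5_2iL_F and 6 lower, with a median difference of 3.05 points. In CpG-poor autosomal DNA P5_2iL_F lay at 80.1% against 81.1% in P5_2iL, and it was lower on every autosome. The tile rule does not see so small a shift. Whether these differences came from the DNA or from the library preparation was not tested, so 1 source of DNA stays open and is not shown. A biological likeness of the 2 culture conditions remains possible and was not tested.

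P5_LCDM was lower than P5_2iL in CpG-poor DNA (under 5 listed cytosines within 100 bp) and higher where 30 or more were listed, but at 20 to 29 it was lower, at 24.2% against 24.8%. Incomplete bisulfite conversion in P5_LCDM might raise levels, but its mitochondrial level differed from that of P5_2iL by only 0.0478 points over 42 shared cytosines, and the mitochondrial genome is an imperfect control. A change of a few chromosomes was not likely, since the CpG-poor level was lower on 19 of 19 autosomes, by differences from -14.1 to -10.3 points. Leukocyte content of P5_2iL as the reference was not excluded. P5_LCDM minus P5_a2iL gave -5.77 points, which counts against it only if P5_a2iL holds no more such cells than P5_LCDM. The content of such cells was not measured, so this comparison cannot decide. The culture condition, which the design names, was not tested.

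The 116 mitochondrial cytosines listed in P5_a2iL had a mean of 4.95%, while the other libraries listed from 69 to 265 with means from 0.0873 to 0.411%. Over the 42 mitochondrial cytosines shared by all libraries P5_a2iL lay at 0.581%.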
